A study of Mus musculus with 24 samples.

How the data were processed

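Gene expression was measured in embryonic mouse jaws at embryonic day 14.5. Per the labels, RNA was extracted with Qiagen RNeasy kits from the distal and the proximal end of the maxilla (upper jaw) and of the mandible (lower jaw), and 5 µg of total RNA per sample was labelled with biotin and hybridised to an Affymetrix mouse genome array. Per the series' design text, Wnt1-Cre;Tgfbr2 fl/+ mice were crossed with Tgfbr2 fl/fl mice. Wnt1-Cre removes floxed sequence in neural crest cells, from which most jaw connective tissue and bone derives. Mutants were recognised by a cleft palate and a calvarial defect and were compared with control littermates. The 24 arrays form 8 groups of 3, by genotype, jaw and end.

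The deposited table holds 1 log2 value per probe set and array, with 1 column for each sample. The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarises probes, and Partek 6.6. The settings of either are not given in the sources used here, and neither is a genome build. That the values are on a log2 scale was taken from the deposited values themselves, which lay between 3.44 and 14.8 on every array, with array medians from 6.93 to 7.00. Values near the lower end of this range are dominated by background, so changes of dim genes are understated. No array of a group duplicated another. The most similar pair of arrays within a group differed by a root mean square of 0.175 (log2).

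Probe sets were named with the platform's annotation table and checked by Entrez identifier against a mouse RefSeq gene table (assembly GRCm38.p6, used only for names and neighbouring genes). Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed here. The 64 array controls among the 45101 were left out. Identifiers matched for 34754 probe sets and no symbol needed an update. Only probe sets with a single symbol were used. They covered 18193 genes, of which 9010 had more than 1 probe set, and the probe set with the highest mean over all arrays stood for the gene. Genes entered the tests when their value exceeded the array's own median in at least 3 of the 24 arrays, which left 12811 genes. Columns that belong to no listed sample numbered 0.

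Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 values, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All 24 arrays in 8 groups entered 1 fit, so that each comparison of 3 against 3 arrays drew on a shared estimate of the spread. Comparisons were mutant against control in each of the 4 regions, the difference of that effect between jaws and between ends, and, within controls, mandible against maxilla, distal against proximal end, and the jaw by end interaction. For the effect averaged over regions, the 4 arrays sharing a genotype and a replicate number were averaged, and the resulting 3 mutant and 3 control averages were compared. This treats the pieces with 1 number as 1 unit, although the number 2 controls differed in Xist (6.49 in the proximal maxilla, 12.4 to 13.0 in the other regions) and so, if the labels are right, did not all come from 1 embryo. The labels do not say whether replicates are separate embryos, litters or pools, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. The median standard error was 0.106 for a single region and 0.0737 for the average of regions (log2).

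A total of 37 gene lists with 796 entries (pathways, patterning genes, cell types of the jaw and of tissues that a dissected piece could include) were fixed before the data were examined, together with the design, the rule for genes to be named and most alternative settings. Of these entries, 665 had a tested gene. Each list was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over lists within a comparison. Camera asks whether a list moved relative to other genes, and fry whether its members moved on balance in 1 direction. The fry value is printed for a few lists that passed it, so a list given without it need not have passed fry. Which members passed is given over all genes tested and, where stated, adjusted over the list alone. The genes named are the largest rises and falls among those past the threshold whose compared values did not overlap (12 each way for the regional average and the control comparisons of jaws and of ends, within each stratum, and 6 each way for single regions), the 6 largest each way for interactions, Tgfbr2, the members of the TGF-beta lists that passed, and up to 4 members of each list described. Where fewer than 3 genes passed in a direction, the 3 with the smallest unadjusted p were taken. Sex-linked genes and genes with only a clone or accession name were skipped.

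Whether replicate numbers pair samples was checked from the deviations of arrays from their group means, before blocked fits were read. The numbers come from the labels, which do not say what they mark. Every same-numbered pair correlated above 0.1 for the distal mandible (0.151 to 0.506), the proximal mandible (0.297 to 0.323), the regional average (0.184 to 0.594) and the control comparison of ends (0.110 to 0.537), so a fit with the number as a block is given there where it changes a call.

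The tests were checked on simulated data made from the means of the 12811 tested genes, with a seeded set of genes changed by known amounts. Noise was drawn independently for genes and arrays, with the same spread of a gene in all groups. Only the regional average had an added effect shared by pieces of a number. Outlying arrays and correlated genes were not imitated, so rates in the real arrays may differ, and the single maxilla regions were not simulated. In the distal mandible comparison 60.0%, 92.9% and 94.3% of genes changed by 0.5, 1 and 2 (log2) were recovered, and 11 of 178 calls (6.18%) were false. For the regional average the shares were 70.0%, 91.4% and 94.3%, with 3.91% false. For the difference between jaws they were 61.7%, 94.3% and 98.6%, with 4.44% false, and for the jaws of controls 86.7%, 95.7% and 95.7%, with 8.37% false. Alternative settings covered the filter on dim genes, the choice of probe sets, the scaling of arrays, the variance model, array weights, a sex covariate, replicate blocks, the arrays entering the fit, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.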

Results

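Expression was profiled in 24 jaw samples from C57B6 mouse embryos at embryonic day 14.5. Mutant embryos carried a Wnt1-Cre driven deletion of Tgfbr2, which encodes the type II TGF-beta receptor, in neural crest cells, and were compared with control littermates. Each maxilla and each mandible had been divided into a distal and a proximal end, giving 8 groups of 3 arrays, and 12811 genes were tested. The series was designed to profile gene expression in the developing mandible and maxilla. The comparisons therefore asked what receptor loss changed in each region, whether the change differed between jaws or ends, and how the regions differed in controls. Changes are given as the log2 difference, mutant minus control unless stated, ± the standard error of the limma fit, with n = 3 arrays per group. Adjusted p-values are limma's with Benjamini-Hochberg adjustment.

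Tgfbr2 itself was measured by a bright probe set in every array. Its mean was 11.9 ± 0.00973 (SD, n = 3) in control and 12.3 ± 0.192 (SD, n = 3) in mutant distal maxilla, and 11.6 ± 0.0903 against 12.4 ± 0.210 (SD, n = 3 each) in proximal maxilla. In the distal mandible the means were 12.1 ± 0.0514 and 12.4 ± 0.0230 (SD, n = 3 each), and in the proximal mandible 11.9 ± 0.0340 and 12.3 ± 0.0447 (SD, n = 3 each). The signal was thus higher in mutants, by 0.45 ± 0.06 in the average of regions (adjusted p = 0.0355, limma, kept in 11 of 20 alternative settings). A call was made in the proximal maxilla (0.78, adjusted p = 8.9e-05) and the proximal mandible (0.32, adjusted p = 0.0472, kept in 8 of 20 alternative settings), while the distal maxilla (0.39, adjusted p = 0.0887) and distal mandible (0.31, adjusted p = 0.119) missed the threshold. These 2 passed in 2 and 3 of 20 alternative settings. A dimmer probe set, at 7.44 to 7.73 in controls, was also higher in the proximal maxilla (0.58, adjusted p = 0.0107), and another lay near background at 4.35 to 4.52 in all groups. Which exon was deleted is not given in the sources used here, so these probe sets do not check the genotype labels.

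The pieces differed in tissue marker lists, also among arrays of the same genotype and region. The 3 maxilla arrays with high muscle means described here were all mutants, so their difference cannot be told apart from genotype. The mean of the olfactory and nasal epithelium list (markers of the lining of the nasal cavity), centred on all arrays, was 1.28 to 1.88 in 5 of the 6 control maxilla arrays and −0.07 in control distal maxilla 2. It was 0.23 and 0.60 in mutant distal maxilla 2 and 3 and 1.47 in mutant proximal maxilla 3. In mutant distal maxilla 1 and in mutant proximal maxilla 1 and 2 it was −0.11, −0.85 and −0.63. The same 3 arrays had skeletal muscle list means of 1.06, 1.84 and 0.85, against −2.06 to −0.71 in control maxilla arrays, and chondrocyte list means of −1.94, −2.02 and −2.18, against −0.02 to 1.46. Fits below that leave out arrays lacking nasal markers drop these 3 mutant arrays only. Control distal maxilla 2, at −0.07 for nasal and −2.06 for muscle markers, was kept. Mutant distal maxilla 1 and mutant proximal maxilla 3 differed most from their group mates (root mean square 0.552 and 0.551, log2, against 0.181 to 0.371 elsewhere).

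**Figure D1:**
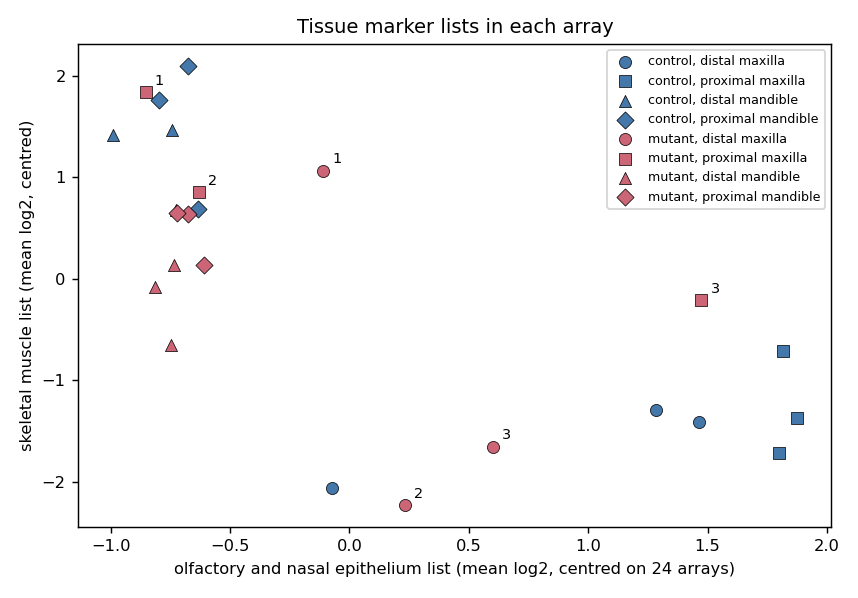
Mean of the olfactory and nasal epithelium list (horizontal) against the mean of the skeletal muscle list (vertical) in each of the 24 arrays, as log2 values centred over all arrays, with colour for genotype, symbols for region and replicate numbers beside the mutant maxilla arrays. Mutant distal maxilla 1 and mutant proximal maxilla 1 and 2 lie apart from the control maxilla arrays, at muscle means of 1.06, 1.84 and 0.85.

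In the distal maxilla, 25 genes passed, 14 higher and 11 lower in mutants. Sned1, which encodes a secreted matrix protein, rose by 1.26 ± 0.24 (adjusted p = 0.0376), and Vit, encoding the matrix protein vitrin, by 1.08 ± 0.17 (adjusted p = 0.00782). The endothelial gene Esm1 and the protease inhibitor gene Tfpi2 rose by 1.06 ± 0.17 and 0.96 ± 0.18, the purinergic receptor gene P2ry12 by 1.17 ± 0.16 and the complement protease gene C1s1 by 0.94 ± 0.17, the last on a probe set shared among related transcripts. Among the falls were Itga9, the integrin alpha 9 subunit (−1.15 ± 0.17, adjusted p = 0.00721), Erg, an endothelial transcription factor (−1.05 ± 0.15, adjusted p = 0.00552), and Mfap4, a protein of elastic fibres (−0.83 ± 0.14, adjusted p = 0.0176). Slc25a35, the matrix protease gene Adamts6 and Sertad4 fell by 1.08, 0.97 and 0.81. P2ry12, Esm1, Tfpi2, Slc25a35 and Adamts6 were below the array median in 1 of the genotypes, where changes are compressed. Alternative settings ended the calls of Sned1 (8 of 20), Tfpi2 (8 of 19), C1s1 (7 of 19), Mfap4 (6 of 20) and Slc25a35 (6 of 19).

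Gene lists in the distal maxilla moved with few single calls. None of the 30 cell cycle genes passed over all genes tested, 9 were lower adjusted over the list alone, and the list median was −0.17 (camera adjusted p = 3.4e-11, adjusted p = 0.29 with an estimated correlation). The 22 genes of hypoxia and glycolysis had a median of 0.26 (camera adjusted p = 6.3e-08, 0.29 with an estimated correlation), with 5 higher adjusted over the list alone. Vegfa, the vascular growth factor, stood at 0.33 (adjusted p = 0.23) and Ddit4, a stress-induced inhibitor of mTOR, at 0.30 (adjusted p = 0.20). Neuron and nasal lists were lower, at medians of −0.79 and −0.60 (camera adjusted p = 0.0013 and 0.0052, 0.78 for both with an estimated correlation), and 0 of their 17 and 11 genes passed. Neither list passed without mutant 2 (0.0504 for both), nor the nasal list without control 1 (0.0917). Palate shelf genes had a median of 0.21 (camera adjusted p = 0.0020, 0.47 with an estimated correlation), with Shox2 at 0.94 (adjusted p = 0.16) and Tbx22 at 1.52 (adjusted p = 0.23), but the list did not pass without mutant 1 (0.0654). Of 20 endothelial genes 1, Erg, fell, and the list as a whole lay at 0.17 (camera adjusted p = 0.0015, 0.78 with an estimated correlation), which rested on mutant 1 (0.794 without it, with array means of 0.33 in mutant 1 and −0.00 and −0.05 in the others). Skeletal muscle genes stood at 0.84 and cartilage genes at −0.68, but their directions turned to lower (camera adjusted p = 0.00268) and higher (camera adjusted p = 0.688) without mutant distal maxilla 1, the array with high muscle and low nasal markers. No member of the TGF-beta pathway list or of the TGF-beta response list passed here.

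The count in the distal maxilla was sensitive to single arrays, from 7 without control 3 to 61 without control 2, and was 16 without the 3 mutant maxilla arrays that lacked nasal markers. With only the 6 arrays compared in the fit it was 1. The split turned to 18 higher and 43 lower without control 2, and to 210 and 354 with array weights.

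In the proximal maxilla, 2984 genes passed, 1558 higher and 1426 lower, and 812 of them changed at least 2-fold. Keratinocyte genes led the rises: Krt25 (4.41 ± 0.64, adjusted p = 0.000315), Krtdap (3.86 ± 0.77, adjusted p = 0.00196) and Dmkn (3.93 ± 0.79, adjusted p = 0.00202). The dermal matrix gene Dpt rose by 4.23 ± 0.85, Hoxd1 by 3.80 ± 0.73 and Them5 by 3.71 ± 0.83. Falls were led by genes of sensory and neural progenitors: the homeobox gene Otx2 (−4.72 ± 1.19, adjusted p = 0.00864), the neurogenic factors Neurod1 (−4.49 ± 1.01, adjusted p = 0.00438), Nhlh2 (−4.43 ± 1.03) and Insm1 (−4.39 ± 1.07), the sulfotransferase gene Sult1e1 (−4.39 ± 0.97) and the claudin gene Cldn9 (−4.08 ± 0.94). Leaving out the 3 mutant maxilla arrays without nasal markers left only mutant 3 in this region. The 6 falls then stood at −0.64 for Otx2, −0.84 for Neurod1, −0.96 for Nhlh2, −0.64 for Insm1, −1.56 for Sult1e1 and −1.08 for Cldn9. The rises stood at 4.23 for Krt25, 3.54 for Dpt, 3.17 for Hoxd1, 3.55 for Dmkn, 3.49 for Krtdap and 3.22 for Them5. These values describe a single mutant piece, so no call is drawn from them.

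Lists of tissue markers followed the array differences described above. Of 29 skeletal muscle genes 17 rose and 0 fell, among them Myog (3.13), Tnnt2 (3.11), Myod1 (2.81) and Tnni1 (2.80) (camera adjusted p = 2.2e-08, 0.42 with an estimated correlation), in mutant arrays of which 2 lacked nasal markers. Cartilage genes fell in 17 of 25 cases, with Matn1 at −5.05, Acan at −3.37, Hapln1 at −3.32 and Col2a1 at −3.11 (camera adjusted p = 6.0e-08, 0.42 with an estimated correlation), and these were also the arrays with chondrocyte list means near −2.02 and −2.18. Of 17 neuron genes 11 fell (Elavl4 −3.04, Ina −2.85, Tubb3 −2.85, Stmn3 −2.83) and of 11 nasal genes 6 fell (Bpifa1 −5.84, Cnga2 −2.49, Gng8 −2.47, Eya1 −1.51), each with adjusted p = 0.34 for the list with an estimated correlation. Macrophage genes rose in 13 of 20 cases, including Lyve1 (1.92), Cd68 (1.15), Fcgr3 (1.14) and C1qa (1.07) (camera adjusted p = 7.2e-06, 0.42 with an estimated correlation). Of 20 endothelial genes 10 rose, such as Tek (1.09), Sox18 (0.65) and Pecam1 (0.56), while Erg fell by 0.77 (camera adjusted p = 8.0e-05, 0.38 with an estimated correlation). Epithelial genes split, with 12 of 27 rising (Krtdap, Krt1 3.28, Krt10 2.41) and 6 falling (Cldn7 −2.73).

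Signalling and patterning genes also changed in the proximal maxilla, in the same arrays. Of 15 hedgehog genes 8 rose and 0 fell, including the ligand Shh (1.88, adjusted p = 0.0084), its transcriptional effector Gli1 (1.03, adjusted p = 0.00036), Osr2 (1.26) and Hhip (0.81) (camera adjusted p = 0.00081, 0.34 with an estimated correlation). Of 26 Wnt genes 10 rose and 1 fell: Dkk2 (1.62), Wnt11 (1.35) and Wnt6 (1.17) were higher and the secreted inhibitor Sfrp1 lower (−1.21) (camera adjusted p = 0.0017, 0.34 with an estimated correlation). Palate shelf genes rose in 9 of 21 cases and fell in 0, with Shox2 at 2.09 (adjusted p = 9.7e-05), Meox2 at 2.08 and Osr1 at 1.84 (camera adjusted p = 0.0024, 0.34 with an estimated correlation). Among tooth genes 10 of 25 rose, such as Lhx8 (2.00) and Dlx2 (1.61), and 2 fell, 1 of them Sox2 (−1.90). Pparg, the adipogenic nuclear receptor, rose by 1.61 and the lipase gene Lpl by 1.53. The neural crest factor Twist2 rose by 2.97 and Foxc1 fell by 1.49.

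Of 19 genes for TGF-beta ligands, receptors and Smads, 6 rose in the proximal maxilla: the co-receptor Tgfbr3 (1.82, adjusted p = 0.00014), Tgfbr2 (0.78), Tgfb2 (0.61, adjusted p = 0.00022), Acvrl1 (0.50), the co-receptor Eng (0.39) and Itgav (0.36). Tgfbr1, the type I receptor, fell by 0.48 (adjusted p = 0.0040). Of 27 TGF-beta response genes 8 rose and 3 fell. The matricellular gene Ccn2 (−1.90, adjusted p = 0.0031), the tendon factor Scx (−0.66) and the feedback inhibitor Pmepa1 (−0.31) were lower, and Acta2 (1.44), Cdkn2b (0.93), Tgfbi (0.56), Snai2 (0.48), Pdgfb (0.43), Col3a1 (0.38), Postn (0.34) and Ski (0.27) were higher. Neither list passed camera (adjusted p = 0.11 and 0.36, 0.34 and 0.65 with an estimated correlation). Acta2 also belongs to the smooth muscle list, of which 7 of 11 genes rose, including Des (2.15). Of 30 cell cycle genes 1 rose, Ccnd3 (0.49), and 5 fell, among them Ccnd1 (−0.29), Kif11 (−0.27) and Mcm2 (−0.26), with a list median of −0.11 (camera adjusted p = 0.0081, 0.57 with an estimated correlation).

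The proximal maxilla count fell to 39 with the nasal and muscle list means as covariates, and to 761 with only the 6 arrays compared in the fit. The main fit takes the spread to be the same in all groups, which may understate it in the maxilla. Mutant maxilla arrays differed from their group mates by a root mean square of 0.298 to 0.552 (log2), against 0.181 to 0.284 in the mandible. Among single arrays it ranged from 1363 without mutant 1 to 3932 without mutant 3.

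**Figure D2:**
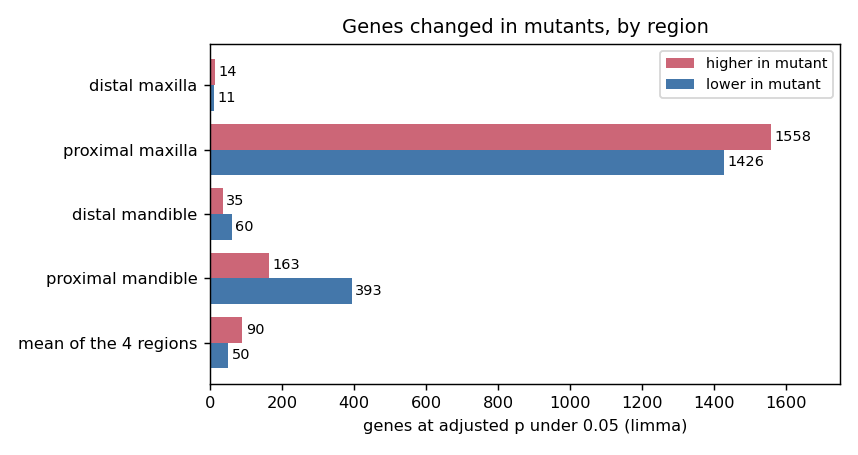
Number of genes past an adjusted p of 0.05 (limma, horizontal axis) that were higher or lower in mutants, for each region and for the average of the 4 regions. The proximal maxilla had 1558 higher and 1426 lower genes, and the distal maxilla 14 and 11.

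In the distal mandible, 95 genes passed, 35 higher and 60 lower. Arg1, the urea cycle enzyme arginase, rose by 2.33 ± 0.38 (adjusted p = 0.00577), the keratinocyte genes Sprr3 and Krt6b by 2.24 ± 0.50 and 2.12 ± 0.43, and the ephrin receptor gene Epha5 by 1.52 ± 0.24. Sned1 and Vit rose again, by 1.74 ± 0.24 and 1.46 ± 0.17 (adjusted p = 0.0017 and 0.000221). Genes of differentiated muscle fell: Atp1b4 (−4.04 ± 0.57, adjusted p = 0.0017), the muscle creatine kinase Ckm (−3.59 ± 0.59, adjusted p = 0.00586) and Sh3bgr (−2.41 ± 0.53). The fatty acid binding protein gene Fabp4 fell by 2.74 ± 0.47, the cytokine gene Il33 by 2.06 ± 0.47 and Tnmd, encoding the tendon membrane protein tenomodulin, by 1.97 ± 0.28 (adjusted p = 0.0017). Of these falls, only Tnmd kept a signal above the array median in both genotypes. Calls were lost in 11 of 19 alternative settings for Il33, 7 of 19 for Sprr3, 5 of 19 for Krt6b and 5 of 18 for Sh3bgr. Without control 2 Sprr3 stood at 1.62 (adjusted p = 0.204) and Krt6b at 1.38.

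Of 15 tendon and ligament genes 3 fell in the distal mandible and 7 were lower adjusted over the list alone. Tnmd, the collagen-binding proteoglycan gene Fmod (−1.48, adjusted p = 0.011) and Scx, the transcription factor of tendon progenitors (−1.28, adjusted p = 0.0038), were those that passed (camera adjusted p = 7.8e-09, 0.16 with an estimated correlation, fry adjusted p = 0.012). Among 35 matrix genes 3 fell, Fmod and the elastic fibre genes Fbln5 (−1.43, adjusted p = 1.3e-06) and Eln (−0.52, adjusted p = 0.023), and 10 were lower adjusted over the list alone (camera adjusted p = 2.1e-10, 0.25 with an estimated correlation). In the TGF-beta response list Scx and Tgfbi (−0.80, adjusted p = 0.0061) fell among 27 genes (camera adjusted p = 0.0012, 0.16 with an estimated correlation). The ligand gene Tgfb2 rose by 0.54 (adjusted p = 0.0020) and was the only 1 of 19 pathway genes to pass. Skeletal muscle genes had a median of −1.27, and 1 of 29, Ckm, passed, with 4 lower adjusted over the list alone (camera adjusted p = 2.3e-11, 0.64 with an estimated correlation). Cartilage genes lay at −1.59 with 0 of 25 passing (camera adjusted p = 6.7e-10, 0.64 with an estimated correlation). Their list mean was −1.76 and −1.56 in mutant 1 and 3 but 0.13 in mutant 2. Controls 1, 2 and 3 stood at 0.60, 0.80 and −0.35, so the genotypes overlapped.

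Hypoxia and glycolysis genes were higher in the mutant distal mandible. Ankrd37 (0.78, adjusted p = 0.025), Vegfa (0.46, adjusted p = 0.027) and the mitochondrial kinase gene Pdk1 (0.45, adjusted p = 0.022) rose among 22 genes, and 11 were higher adjusted over the list alone (camera adjusted p = 2.6e-08, 0.20 with an estimated correlation, fry adjusted p = 0.012). The cell cycle list median was −0.10 with 0 of 30 genes passing (camera adjusted p = 1.3e-07, 0.35 with an estimated correlation). Macrophage genes stood at −0.29 (camera adjusted p = 8.0e-06, 0.65 with an estimated correlation), and epithelial genes at 0.56 (camera adjusted p = 0.0012, 0.90 with an estimated correlation), with 0 of 20 and 0 of 27 passing. The epithelial list rested on control 2, with a list mean of −0.50 against 0.04 and 0.69 in the other controls and 0.25 to 0.87 in mutants, and did not pass without it (0.399). Pparg rose by 1.25 (adjusted p = 0.0098) while Fabp4, a target of it in fat cells, fell.

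With the replicate number as a block, 354 genes passed in the distal mandible, the 95 included, and of these 180 were higher and 174 lower, so the excess of lower genes was not kept. With array weights 530 were higher and 454 lower. Among single arrays the count ranged from 35 without mutant 1 to 116 without mutant 2, and it was 292 when only the 12 mandible arrays entered the fit.

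In the proximal mandible, 556 genes passed, 163 higher and 393 lower. Fam162b rose by 1.85 ± 0.26 (adjusted p = 0.00106), Sned1 by 1.72 ± 0.24, Vit by 1.56 ± 0.17 (adjusted p = 5.99e-05), the ferroxidase gene Cp by 1.43 ± 0.37, Epha5 by 1.32 ± 0.24, and Tnfrsf11b, encoding osteoprotegerin, the decoy receptor that restrains osteoclasts, by 1.38 ± 0.32 (adjusted p = 0.0219). Among falls were Fabp4 (−3.40 ± 0.47, adjusted p = 0.00111), the cartilage matrix gene Cilp (−2.25 ± 0.24, adjusted p = 5.99e-05) and the tendon and muscle attachment gene Thbs4 (−2.24 ± 0.62, adjusted p = 0.048). The muscle genes Atp1b4, Ckm and Myh7 fell by 3.17 ± 0.57, 2.88 ± 0.59 and 2.37 ± 0.60. Thbs4 lost its call in 11 of 20 alternative settings (adjusted p up to 0.164) and Cp in 7 of 20.

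Of 30 cell cycle genes in the proximal mandible, 21 fell and 0 rose, including the replication licensing gene Cdc6 (−0.56, adjusted p = 0.020), the cyclin gene Ccne1 (−0.46, adjusted p = 0.010), the mitotic kinesin gene Kif11 (−0.45) and the mitotic kinase gene Aurka (−0.44), and 26 were lower adjusted over the list alone. The list had camera adjusted p = 1.2e-18, 0.10 with an estimated correlation, and fry adjusted p = 5.3e-05. Its median was −0.30 as deposited and −0.26 and −0.25 after quantile normalization and median centring. The list mean was −0.26 in mutant 1 and −0.11 and −0.12 in mutant 2 and 3, and the list passed without mutant 1 (camera adjusted p = 2.8e-20). Hypoxia and glycolysis genes moved the other way, with Ankrd37 (0.72), Vegfa (0.40), Pdk1 (0.38) and Ddit4 (0.37) rising among 22 (camera adjusted p = 1.5e-05, 0.48 with an estimated correlation).

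Tendon genes fell in 3 of 15 cases, Thbs4, Scx (−1.39, adjusted p = 0.0013) and Fmod (−1.28, adjusted p = 0.013) (camera adjusted p = 0.0041, 0.78 with an estimated correlation). In the matrix list Fbln5 (−1.92, adjusted p = 1.9e-08), Fmod, Eln (−0.74, adjusted p = 0.0012) and the fibrillin gene Fbn2 (−0.50, adjusted p = 0.036) fell among 35, though the list did not pass (camera adjusted p = 0.13). Of the TGF-beta pathway list, Tgfb2 (0.69, adjusted p = 0.00016), Tgfbr2 (0.32) and Eng (0.26, adjusted p = 0.041) rose (camera adjusted p = 0.028, 0.15 with an estimated correlation), and the list did not pass without control 2 (0.0567), control 3 (0.0565) or mutant 1 (0.128). In the response list Scx and the Smad feedback inhibitor Ldlrad4 (−0.61, adjusted p = 0.0055) fell and Snai2 rose (0.31, adjusted p = 0.030). The BMP antagonist gene Grem1 fell by 1.54 (adjusted p = 0.00070) and Bmp2 rose by 0.47 (adjusted p = 0.041). Endothelial genes Cldn5 (−0.60), Erg (−0.59), Icam2 (−0.50) and Kdr (−0.44) fell, 4 of 20 in that list. Skeletal muscle genes had a median of −0.95 with 2 of 29 falling (camera adjusted p = 0.0035), and cartilage and osteoblast genes lay at 0.87 and 0.26 with 0 of 25 and 1 of 20 rising (camera adjusted p = 0.00061 and 0.0014), each 0.78 with an estimated correlation. Without control 3 the cartilage list did not pass (0.0897), its array mean being −0.98 in that array and 0.39 and 0.65 in the other controls, and without mutant 1 the osteoblast list did not (0.0702). The muscle list did not pass without mutant 2 (0.17) or control 3 (0.0565). The neuron list stood at −0.78 with 1 of 17 genes falling (camera adjusted p = 0.034, 0.78 with an estimated correlation, 0.0707 with the replicate number as a block). It rested on control 3, with a list mean of 0.65 against −1.02 and −0.63 in the other controls, and did not pass without it (0.636) or without mutant 2 or 3 (0.123 and 0.106).

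With the replicate number as a block, 1356 genes passed in the proximal mandible, the 556 included, with 378 higher and 978 lower. The split of 29.3% higher among the calls was 45.4% after quantile normalization and 47.6% after median centring. The excess of lower genes was thus smaller under these scalings. It was absent without mutant 1, whose upper quartile was 9.16 against 9.30 to 9.41 in the other arrays (92 higher and 72 lower), and with only the 6 arrays compared in the fit (92 and 70), and larger without mutant 2 (100 and 435) or mutant 3 (88 and 354). The count ranged from 125 without control 3 to 535 without mutant 2.

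Averaged over the 4 regions, 140 genes passed, 90 higher and 50 lower. With the replicate number as a block 183 genes passed, 87 higher and 96 lower, and 88 of the 140 were among them. Sned1 rose by 1.57 ± 0.13 (adjusted p = 0.0151), Vit by 1.29 ± 0.10 (adjusted p = 0.0136) and Efemp1, encoding the elastic fibre associated protein fibulin 3, by 1.28 ± 0.14 (adjusted p = 0.0229). Fbln5, encoding fibulin 5, fell by 1.16 ± 0.05 (adjusted p = 0.00286), Fmod by 1.10 ± 0.17, Itga9 by 1.07 ± 0.14 and Mfap4 by 0.92 ± 0.09. With the replicate number as a block Efemp1 (adjusted p = 0.0505), Fmod (adjusted p = 0.0795) and Avpr1a (adjusted p = 0.0586) no longer passed. Fmod rests on a probe set that may bind other transcripts.

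Further rises were Fam162b (1.30), the synuclein gene Sncg (1.28), the vasopressin receptor gene Avpr1a (1.28), Epha5 (1.10), the epithelial protease gene Tmprss11a (1.07), Zfp804a (1.07), Pparg (1.05, adjusted p = 0.00746), Arhgap20 (1.03) and Lrrtm4 (1.02). Further falls were Fabp4 (−2.10 ± 0.21, adjusted p = 0.0171), Il33 (−1.49), Sult1c1 (−1.44), the potassium channel gene Kcna5 (−1.27), Arfgef3 (−1.05), Homer2 (−0.98), the neuronal ubiquitin hydrolase gene Uchl1 (−0.97) and Caln1 (−0.96). Sult1c1 stood at 0.09 in the average of the mandible regions alone, so its fall came from the maxilla. Many of these calls depended on the setting: Tmprss11a lost its call in 9 of 19 settings, Fmod in 9 of 20, Avpr1a, Epha5, Il33 and Arfgef3 in 8 of 19 each, Lrrtm4 and Homer2 in 8 of 20, Uchl1 in 7 of 20 and Sult1c1 in 7 of 19. In 1 more setting Sult1c1 turned direction and did not pass. Losses were 6 of 20 for Itga9 and Kcna5, 6 of 19 for Sncg, 6 of 18 for Caln1, 5 of 20 for Efemp1 and 5 of 19 for Fam162b. In the TGF-beta lists Tgfbr3 (0.76, adjusted p = 0.044), Tgfb2 (0.54, adjusted p = 0.025) and Tgfbr2 rose, and Ltbp2, a latent TGF-beta binding protein (−0.67, adjusted p = 0.017), and Scx (−0.86, adjusted p = 0.016) fell. From other lists, Dlx2 (0.70, adjusted p = 0.030), Dlx1 (0.83, adjusted p = 0.049), Shox2 (0.88, adjusted p = 0.041), Ambn (0.90, adjusted p = 0.043) and the Wnt inhibitor gene Dkk2 (0.80, adjusted p = 0.037) rose.

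Among lists in the regional average, cell cycle genes had a median of −0.18 with 0 of 30 passing and 9 lower adjusted over the list alone (camera adjusted p = 7.7e-10, 0.63 with an estimated correlation). Neuron genes lay at −0.90, with 1 of 17 falling and 11 lower adjusted over the list alone (camera adjusted p = 1.5e-07, 0.63 with an estimated correlation). Nasal genes lay at −0.54 (camera adjusted p = 0.0015, 0.63 with an estimated correlation). Nasal list means overlapped in the mandible (controls −0.99 to −0.64, mutants −0.82 to −0.61), so this fall came from the maxilla pieces. Neuron list means overlapped in the distal mandible (controls −0.79 to −0.62, mutants −0.74 to −0.65). In the proximal mandible the neuron list rested on control 3. Tooth genes lay at 0.25 with 2 of 25 rising (camera adjusted p = 4.7e-05, 0.63 with an estimated correlation) and hypoxia and glycolysis genes at 0.20 with 0 of 22 passing (camera adjusted p = 5.8e-05, 0.64 with an estimated correlation). The count of 140 was 0 with nasal and muscle list means as covariates, and between 6 without control 1 and 341 without mutant 3, where 130 were higher and 211 lower. In the mandible regions alone 114 were higher and 132 lower, so the excess of higher genes was not kept in all settings.

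Across regions, 8 genes passed in all 4, each in the same direction. This number rests on the distal maxilla, where 25 genes passed, 7 without control 3 and 1 with only the 6 arrays compared. That 1 gene was P2ry12, which kept its call in 19 of 19 settings and is not among the 8. None of the 8 therefore passed there with only the 6 arrays compared. The call there was lost in 8 of 20 settings for Sned1, 6 for Mfap4 and 2 each for Vit and Itga9. Fbln5, Col8a2, H2az2 and Tmem255a were not followed over the settings there. In the order distal maxilla, proximal maxilla, distal mandible and proximal mandible, Sned1 rose by 1.26, 1.58, 1.74 and 1.72 (± 0.24) and Vit by 1.08, 1.04, 1.46 and 1.56 (± 0.17). Fbln5 stood at −0.80, −0.51, −1.43 and −1.92 (± 0.11), Itga9 at −1.15, −0.93, −1.16 and −1.04 (± 0.17), Mfap4 at −0.83, −0.65, −0.99 and −1.22 (± 0.14) and the collagen gene Col8a2 at −0.64, −1.14, −0.76 and −0.67 (± 0.13). The histone variant gene H2az2 stood at −0.62, −0.73, −0.58 and −0.69 (± 0.10) and Tmem255a at −0.53, −0.29, −0.66 and −0.68 (± 0.095). The ends of the mandible shared 13 higher genes (0.445 expected for independent lists) and 31 lower genes (1.84 expected), and 0 changed in opposite directions. The proximal maxilla and proximal mandible shared 60 higher and 68 lower genes (19.8 and 43.7 expected), and 25 went opposite ways. Each region had its own control arrays. Whether pieces of different regions came from the same embryos is not given in the sources used here, so these lists need not be independent.

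**Figure D3:**
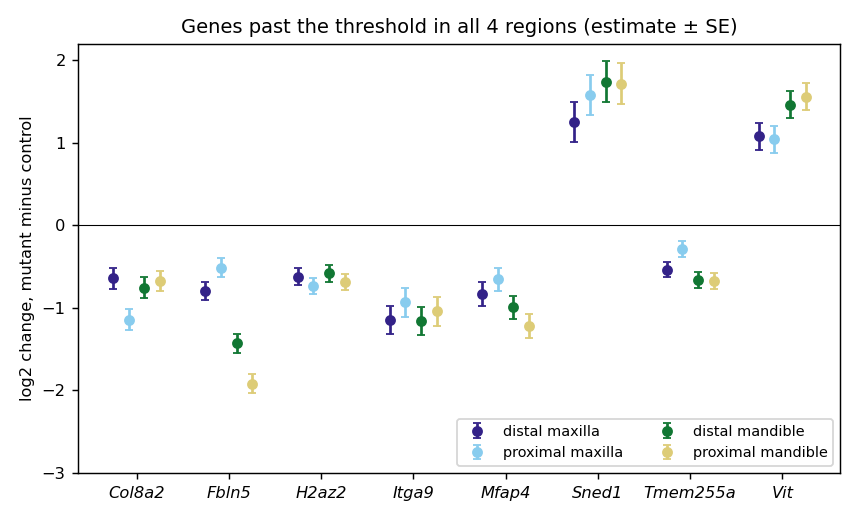
Log2 change (mutant minus control, points) with its standard error (bars) in each region for the 8 genes past the threshold in all 4 regions. Sned1 and Vit lie above 0 and the other 6 genes below it, with the widest spread between regions for Fbln5, from −0.51 to −1.92.

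The genotype effect differed between jaws for 1058 genes, 503 with a more positive and 555 with a more negative effect in the mandible. This balance turned with scaling, to 690 and 595 after quantile normalization and 701 and 541 after median centring, and was 22 and 45 without the 3 mutant maxilla arrays that lacked nasal markers. Muscle genes led the negative side, with Myh8 (−4.81 ± 1.12, adjusted p = 0.0187), Atp1b4 (−4.32 ± 0.57, adjusted p = 0.00156), Tceal7 (−3.97 ± 0.90), Ttn (−3.80 ± 1.05), Tnnt3 (−3.78 ± 0.80) and Smpx (−3.78 ± 0.92). Of 29 muscle genes 24 had a more negative effect in the mandible (camera adjusted p = 4.3e-17, 0.42 with an estimated correlation), where muscle genes were lower in mutants, while in the maxilla they were higher in the arrays lacking nasal markers. On the positive side were the sulfotransferase genes Sult1e1 (3.38 ± 0.97), Sult1c1 (3.06 ± 0.55, adjusted p = 0.00835) and Sult1d1 (2.79 ± 0.82), with Uncx (3.22 ± 0.94), Trim66 (3.18 ± 0.81) and Svopl (3.03 ± 0.85). All 6 were below the array median in the mandible. The calls of Sult1d1 and Uncx were lost in 24 of 36 alternative settings each, of Sult1e1 in 22 of 36 and of Svopl in 21 of 35, while Trim66 kept its call in 30 and Sult1c1 in 34 of 36. That of Ttn was lost in 15 of 37, and its direction turned in 1 more.

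Tendon genes had a more negative effect in the mandible in 6 of 15 cases, including Thbs4 (−3.74, adjusted p = 0.0061), Kera (−2.70), Tnmd (−1.56) and Scx (−0.96, adjusted p = 0.014) (camera adjusted p = 6.8e-06, 0.42 with an estimated correlation). So did 7 of 35 matrix genes, among them Fbln5 (−1.02, adjusted p = 0.00027) and Col6a1 (−0.94), and the response genes Tgfbi (−0.98, adjusted p = 0.0019), Timp3 (−0.61), Ldlrad4 (−0.47) and Pdgfb (−0.33). Palate genes Meox2 (−2.36), Meox1 (−1.38), Shox2 (−1.28) and Osr1 (−1.01) were 4 of 21 on the same side (camera adjusted p = 0.0030, 0.42 with an estimated correlation). In the pathway list the effect was more negative for Tgfbr3 (−0.81) and more positive for Tgfbr1 (0.37). Nasal genes had a more positive effect in 5 of 11 cases (Cnga2 1.88, Gng8 1.82). The count was 67 without the 3 mutant maxilla arrays that lacked nasal markers and 9 with nasal and muscle list means as covariates.

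No gene had a genotype effect that differed between distal and proximal ends (0 of 12811, limma, smallest adjusted p = 0.541), with 982 at an unadjusted p under 0.05 where 640.55 would be expected by chance. With array weights limma called 1140 genes and with trended robust variances 0. Without mutant distal maxilla 1 it called 116, so the result of 0 rests on that array being kept. The smallest unadjusted p on the distal side belonged to Fsd1 (0.32 ± 0.07), Mtmr7 (0.96 ± 0.22) and Col8a1 (1.05 ± 0.25), and on the proximal side to Vstm2b (−0.56 ± 0.12), Krt25 (−2.94 ± 0.64) and Mfge8 (−0.30 ± 0.07), and none of them passed. By list, the 19 TGF-beta pathway genes had a median of −0.08, a less positive effect distally (camera adjusted p = 0.00037, 0.018 with an estimated correlation), with Tgfbr3 at −0.80 and Itgav at −0.23. Macrophage genes (list mean −0.44) and muscle genes (list mean −0.89) passed camera (adjusted p = 7.8e-11 and 1.0e-08) but not with an estimated correlation (0.25 and 0.33).

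**Figure D4:**
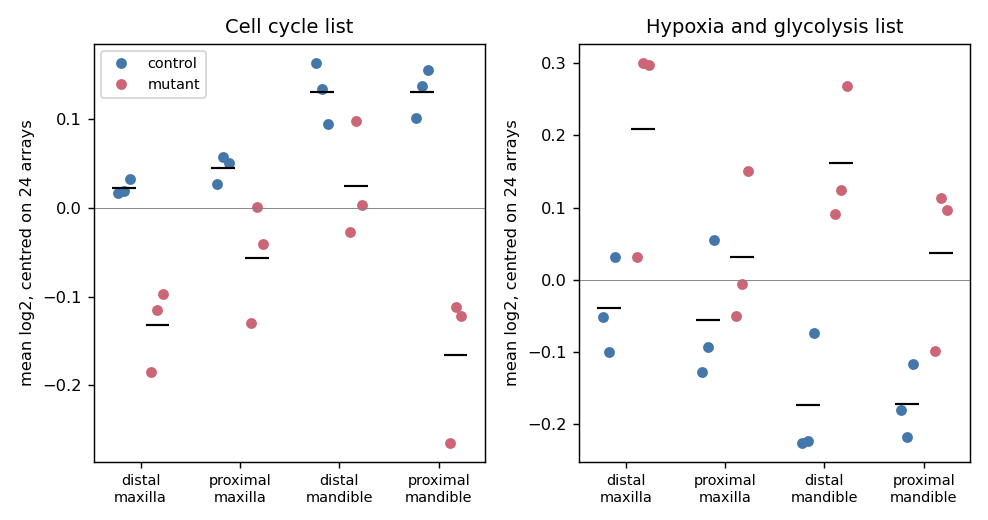
Mean log2 value of the cell cycle list (left) and of the hypoxia and glycolysis list (right) in each array (points, 3 per group, centred over 24 arrays) with group means (lines), by region and genotype. In each region the mutant mean lies below the control mean for the cell cycle list and above it for hypoxia and glycolysis.

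In control embryos the mandible and maxilla differed in 4639 genes, 2160 higher in the mandible and 2479 higher in the maxilla, a balance that turned after quantile normalization (2643 and 2519) and median centring (2773 and 2419). Hand2, the transcription factor that marks the lower jaw, was 5.24 ± 0.26 higher in the mandible (adjusted p = 9.35e-10). The other leading mandible genes were those of contracting muscle and its attachments: Myh8 (4.77 ± 0.79), Ttn (4.18 ± 0.74), Tceal7 (4.05), Tnnc2 (4.04), Neb (3.87), Smpx (3.84), Myom2 (3.81), Atp1b4 (3.79), Thbs4 (3.77), Sln (3.77) and Myh3 (3.74). On the maxillary side were genes of the nasal cavity and olfactory lineage: Bpifa1, an airway secretory protein (−7.26 ± 1.07, adjusted p = 5.58e-05), Otx2 (−5.91 ± 0.84), Insm1 (−5.50), Serpinb11 (−5.34), Neurod1 (−5.30), the ciliary dynein gene Dynlrb2 (−5.24), Sult1e1 (−5.11), Fezf1 (−4.98), Lhx2 (−4.80), Fstl5 (−4.73), Cldn9 (−4.70) and Sp8 (−4.69).

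The lists followed these leaders. Of 29 muscle genes 28 were higher in the mandible and 1 lower (camera adjusted p = 1.9e-14, 0.30 with an estimated correlation), 13 of 17 neuron genes were lower (Stmn3 −3.95, Elavl4 −3.54) and 10 of 11 nasal genes were lower (Foxj1 −3.77), with adjusted p = 0.30 and 0.24 with an estimated correlation. Osteoblast genes were higher in the mandible in 15 of 20 cases, including Mmp13 (1.69), Ifitm5 (1.31), Panx3 (1.29) and Omd (1.16) (camera adjusted p = 1.8e-05, 0.34 with an estimated correlation), and 5 of 7 osteoclast genes were higher too, among them Acp5 (1.69) and Mmp9 (1.39). Of the 14 tested genes of mandibular patterning downstream of endothelin 1 and Dlx5/6, 10 were higher in the mandible and 1 lower, with Pitx1 at 1.79, Sim2 at 1.72 and Nkx2-3 at 1.10 (camera adjusted p = 0.00036, 0.082 with an estimated correlation). In the maxillary patterning list 7 of 14 were lower in the mandible, including Pax7 (−1.62) and Pax3 (−1.10), but Dlx1 (2.45) and Dlx2 (1.95) were higher. Alx1, a factor of frontonasal mesenchyme, was lower (−2.69, adjusted p = 1.59e-05). Of the epithelial list 15 of 27 were lower in the mandible (Sprr1a −3.30, Cldn3 −2.85).

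TGF-beta genes differed between control jaws in both directions. Tgfb1 (0.60), Itgav (0.45), Tgfb3 (0.37), Acvrl1 (0.29), Tgfbr2 (0.24) and Ltbp1 (0.24) were higher in the mandible, and Ltbp2 (−0.67), Tgfb2 (−0.32), Ltbp4 (−0.32), Tgfbr1 (−0.29) and Smad4 (−0.16) were lower. Of 27 response genes 12 were higher and 4 lower. The higher ones were Acta2 (1.17), Scx (0.73), Col1a1 (0.61), Bambi (0.60), Timp3 (0.38), Ldlrad4 (0.34), Pdgfb (0.33), Postn (0.24), Snai2 (0.20), Col3a1 (0.19), Ski (0.19) and Col1a2 (0.16), and the lower ones Ccn2 (−0.95), Ltbp2, Snai1 (−0.44) and Tgif1 (−0.25).

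Distal and proximal ends of control jaws differed in 1088 genes, 640 higher distally and 448 higher proximally. Distal ends were richer in genes of stratified epithelium: Them5 (3.89 ± 0.59, adjusted p = 0.00077), Krt1 (3.12 ± 0.55), Krtdap (2.90 ± 0.54), Krt6a (2.83), the desmosomal cadherin genes Dsg1a (2.82) and Dsc1 (2.30), Csta1 (2.62), Sprr1a (2.60), Sdr16c6 (2.51) and Rptn (2.32). Alx1 was 2.84 ± 0.34 higher (adjusted p = 0.000136) and the neuropeptide gene Nts 2.65 ± 0.33 higher. Proximal ends had more Barx1, a homeobox gene of the molar region (−2.30 ± 0.39, adjusted p = 0.00169), Nr2f1 (−1.82 ± 0.27, adjusted p = 0.000628), Sim2 (−2.35), Shisa3 (−2.42 ± 0.38), the intermediate filament gene of peripheral neurons Prph (−1.89), Cyp1b1 (−1.72), Grp (−1.64), Kcnd2 (−1.57), Elavl2 (−1.44), Chgb (−1.42), Crym (−1.40) and Ebf2 (−1.21). Prph and Ebf2 each lost their call in 10 of 24 alternative settings.

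The fixed list of distal jaw patterning genes had 7 of 12 members higher distally and 0 lower, led by Alx1, Msx2 (1.59, adjusted p = 0.0042), Isl1 (1.49) and Pax3 (1.26), and held with an estimated correlation (camera adjusted p = 2.9e-08, 0.033 with an estimated correlation). Its counterpart of proximal patterning genes split, with 4 of 11 higher distally, such as Dlx2 (0.97), and 2 lower, Barx1 and Pitx1 (−0.81) (camera adjusted p = 0.47). Of 27 epithelial genes 18 were higher distally and 0 lower (camera adjusted p = 1.2e-14, 0.15 with an estimated correlation). Signalling genes lay on the same side: 13 of 26 Wnt genes, including Wnt5a (1.57), Wnt6 (1.11), Sp5 (1.08) and Lef1 (0.99), and 8 of 15 hedgehog genes, including Shh (2.14), Foxf2 (1.24), Hhip (0.82) and Gli1 (0.53), were higher distally and 1 of each list was lower (camera adjusted p = 3.5e-08 and 5.4e-06, 0.066 and 0.092 with an estimated correlation). Of tooth genes 12 of 25 were higher distally, for example Sostdc1 (1.47). In the TGF-beta lists Ltbp2 (0.86), Tgfb2 (0.34), Itgav (0.27), Tgfbr2 (0.21, kept in 9 of 24 alternative settings) and Ski (0.20) were higher distally, and Scx (−0.68) and Lox (−0.37) lower. With the replicate number as a block 1677 genes passed, or 1912 with genotype and number together, and the matrix list (camera adjusted p = 0.044, 7 of 35 genes higher and 2 lower) no longer passed (0.0962 and 0.0793), nor did it in 7 of 12 fits without 1 array. The count was 534 without control distal maxilla 2, the control maxilla array with the lowest nasal markers, and 659 without control proximal maxilla 1.

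**Figure D5:**
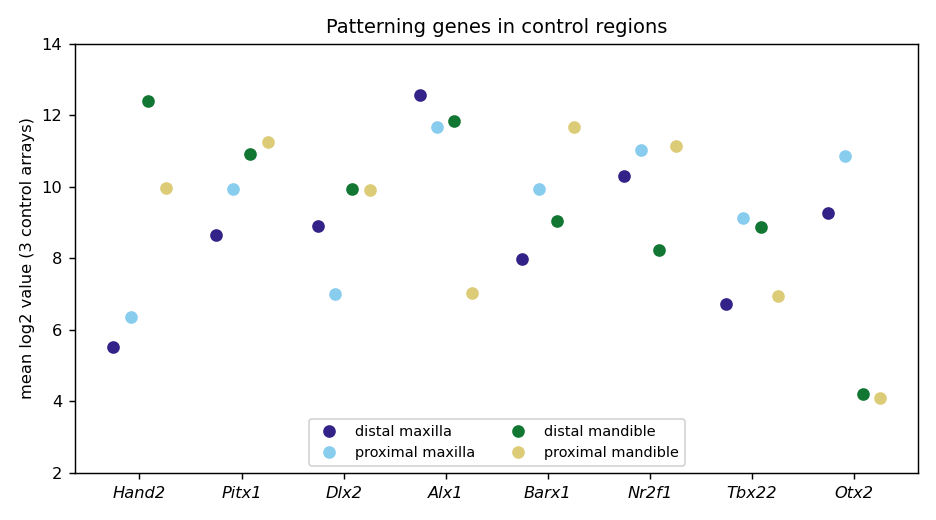
Mean log2 value over the 3 control arrays of each region for 8 transcription factor genes. Hand2 lies at 12.4 and 9.96 in the distal and proximal mandible and at 5.53 and 6.37 in the maxilla, and Alx1 is lowest in the proximal mandible, at 7.05.

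The difference between ends depended on the jaw for 514 genes in controls. Distal minus proximal was more positive in the mandible for 142 and in the maxilla for 372. A negative interaction, as in the 372, can come from a proximal excess in the mandible as well as from a distal excess in the maxilla. The palate gene Tbx22 was higher distally in the mandible (8.89 against 6.95) and proximally in the maxilla (9.14 against 6.74), an interaction of 4.35 ± 0.64 (adjusted p = 0.00135). Alx1 (3.90 ± 0.68) and Hand2 (3.29 ± 0.52) also had a larger distal excess in the mandible, as did the mitochondrial creatine kinase gene Ckmt1 (3.23 ± 0.71), Qrfpr (2.56 ± 0.24) and Ctxn3 (2.35 ± 0.56, lost in 6 of 23 settings). The opposite interaction was seen for the osteocyte genes Dmp1 (−3.73 ± 0.77) and Phex (−3.24 ± 0.75), for Vit (−2.89 ± 0.23, adjusted p = 3.48e-06), Srpx2 (−2.72 ± 0.37), the antisense transcript Dlx1as (−3.74 ± 0.79) and Egr3 (−3.19 ± 0.54), whose other probe set had the opposite sign.

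Osteoblast and bone matrix genes took part broadly, with a negative interaction in 12 of 20 and a positive one in 0 (camera adjusted p = 3.3e-16, 0.063 with an estimated correlation, fry adjusted p = 0.00029). Ifitm5 (−2.39) and Omd (−2.06) were among the 12, beside Dmp1 and Phex. The list mean was highest in the proximal mandible of controls (0.68 to 1.08). It was −0.26 to −0.12 in the distal mandible and −1.10 to 0.21 in the maxilla. Dmp1 was measured at 12.6 in the proximal mandible, 9.87 in the distal mandible, 10.9 in the distal maxilla and 9.89 in the proximal maxilla. Osteoclast genes followed with a negative interaction in 3 of 7 (Atp6v0d2 −1.67). Of 35 matrix genes 10 had a negative interaction, such as Col1a1 (−1.87), Tnc (−1.80) and Lox (−1.08) (camera adjusted p = 4.6e-10, 0.16 with an estimated correlation). Maxillary patterning genes Nr2f1 (−2.17), Shox2 (−2.02), Dlx2 (−1.87) and Irx5 (−0.96) were 4 of 14 with a negative interaction. The immediate early genes Egr2 (−2.53) and Egr1 (−1.49) were among 6 of 24 with a negative interaction. In the TGF-beta lists Tgfb1 (−1.72, adjusted p = 0.0046), Ltbp4 (−0.72), Itgav (−0.44), Col1a1, Cdkn2b (−1.09), Lox and Col1a2 (−0.44) had negative interactions. The share of positive interactions was 27.6% as deposited and 39.6% after median centring, and the count fell to 183 without control proximal mandible 1.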

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

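The tests of the proximal maxilla count, of varying muscle content, of muscle in each mandible end, of handling and of the cell cycle by jaw were chosen only after their result was seen, and the other tests here before it.

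The mutant minus control difference itself differed between jaws for 1058 genes by a direct test. The count was far lower with nasal and muscle list means as covariates, so tissue content is not parted from genotype here. The largest differences more positive in the mandible were Sult1e1 (3.38), Uncx (3.22), Trim66 (3.18), Sult1c1 (3.06), Svopl (3.03) and Sult1d1 (2.79). Calls were lost for Sult1d1 and Uncx in 24 of 36 alternative settings each, for Sult1e1 in 22 of 36 and for Svopl in 21 of 35. More negative in the mandible were Myh8 (−4.81), Atp1b4 (−4.32), Tceal7 (−3.97), Ttn (−3.80), Tnnt3 (−3.78) and Smpx (−3.78). In controls, the difference between ends depended on the jaw for 514 genes by the same kind of test. Distal minus proximal was more positive in the mandible for Tbx22 (4.35), Alx1 (3.90), Hand2 (3.29), Ckmt1 (3.23), Qrfpr (2.56) and Ctxn3 (2.35). It was more positive in the maxilla for Dlx1as (−3.74), Dmp1 (−3.73), Phex (−3.24), Egr3 (−3.19), Vit (−2.89) and Srpx2 (−2.72).

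With 3 against 3 arrays there are 10 splits of the samples, too few for a share under 0.05. The real split gave 2984 genes in the proximal maxilla (highest other 12), 95 in the distal mandible (6), 556 in the proximal mandible (0), 140 in the regional average (1) and 1058 for the difference between jaws (0), and in each of these 1 of 10 splits reached the real count. In the distal maxilla 2 of 10 splits reached 25 genes, the other with 133, which joins mutant 1 to control 1 and 3. For the difference between ends all 10 of 10 splits gave 0. In controls, 1 of 100 splits reached the real count for jaws (4639, highest other 2798), ends (1088, highest other 358) and their interaction (514, highest other 358). This argues against a random division of the arrays without pairing for jaws and for ends. For the interaction it decides less, since these splits also remove the difference between ends itself. They cannot show that this difference depends on the jaw. A split that exchanges the ends in 1 jaw would give the 1088 genes of the ends, and it was not among the 100 drawn. Only 16, 15 and 18 other splits part every pair of samples, too few for a share under 0.05, and their highest counts were 758, 53 and 53.

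The 1st pattern weighed is the large number of genes in the proximal maxilla (2984, against 25, 95 and 556). If other tissue in or missing from the mutant pieces were the cause, the mutant array with nasal markers should be shifted less than the other 2, and its median signed shift over the 2984 genes was 0.333 against 0.752 and 0.677, a ratio of 0.466. These genes were called from the same arrays, so the ratio decides nothing and this explanation stays open. Leaving out the 3 mutant maxilla arrays lacking nasal markers leaves a single mutant array in this region, which cannot decide between the explanations. Scaling of the arrays is argued against, since the count stayed at least 5.82 times that of the proximal mandible under quantile normalization and median centring. A larger genotype effect in this region stays open: 39 genes passed with nasal and muscle list means as covariates, but there the covariates vary together with genotype and may remove its effect too. Different tissue content could itself follow from the mutation or from where the pieces were divided, and the labels do not part these.

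The 2nd pattern is the lower muscle signal in the mutant mandible. Less muscle tissue would lower early muscle genes and contractile genes alike. In the distal mandible 23 contractile genes had a median of −1.53 and 5 early genes −0.07, a difference of −1.46 (SD over contractile genes 0.920). Early genes there ran from −0.03 (Myod1) to −0.88 (Mymk), and contractile genes from −0.44 (Tnnt1) to −3.71 (Myh8). These ranges overlap and the SD holds no error of the arrays, so less muscle tissue alone is not excluded there. In the proximal mandible the difference was −0.52 (SD 0.641), inside its spread, and for both ends together −0.661 (SD 0.756), which decides nothing. Muscle content varying between pieces whatever the genotype stays open. That 6 of 6 mutant mandible arrays lay below the lowest control array of their region restates the pattern, the gap in the proximal mandible was small (up to 0.648 in mutants, 0.681 in the lowest control), and muscle list means ran from −2.23 to 1.84 among the mutant maxilla arrays. Later differentiation of muscle may lower contractile genes alone, and was not tested.

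The 3rd pattern is the lower cell cycle list, whose array mean was lower in 12 of 12 mutant pieces than in the control piece of the same number, while the hypoxia and glycolysis mean was higher in 12 of 12. Numbers were not taken as pairs in the maxilla, and pieces of 1 number need not be independent. Without pairing, cell cycle means overlapped in the distal mandible (mutant 2 0.0982, control 3 0.0948). Hypoxia and glycolysis means overlapped in the distal maxilla (mutant 1 0.0311, control 3 0.0317) and in the proximal maxilla (mutant 1 and 2 −0.0499 and −0.0061, control 3 0.0549). Handling of the mutant pieces before RNA extraction, which would raise immediate early and heat shock genes, stays open. That list's median exceeded 0.1 in 0 of 4 regions, but its members went both ways, which decides nothing, and in the proximal maxilla all 3 mutant list means (0.08 to 0.17) lay above those of the controls (−0.33 to −0.08). With nasal and muscle covariates the mean of the regional medians was −0.168 (SD over regions 0.119) and without them −0.172. In the mandible it was −0.239 (SD 0.135) with covariates and −0.203 without. Muscle list means moved with genotype there (6 of 6 mutant arrays below the lowest control of their region). The covariates therefore cannot decide, and nasal and muscle content stays open in the mandible. In the maxilla it was −0.0973 (SD 0.0667) with them and −0.140 without, and −0.0501 in the proximal maxilla, where it had been −0.106, so content stays open there. Scaling alone is argued against, since the mean stayed at −0.153. A slower cell cycle or a shift in cell types is consistent with these values, and neither was tested.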

How the results depend on the processing

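The settings with the 3 mutant maxilla arrays left out, with nasal and muscle covariates, and with mandible arrays or regions alone were chosen only after the results were seen. Over all settings, named genes kept direction and side of the threshold in 3206 comparisons, were weaker in 464, stronger in 25 and reversed in 7, and for lists these were 2322, 433, 0 and 5. Array quality weights changed counts to 564 (distal maxilla), 6205 (proximal maxilla), 984 (distal mandible), 1693 (proximal mandible), 675 (regional average), 3755 (difference between jaws), 1140 (difference between ends), 6993 (control jaws), 2436 (control ends) and 2002 (control interaction). Nasal and muscle covariates gave 52, 39, 274, 1330, 0 and 9 for the first 6 of these, and leaving out the 3 mutant maxilla arrays, with 1 proximal mutant array left that is assumed to vary like the other groups, gave 16 in the distal maxilla, 159 in the proximal maxilla, 67 for jaws and 7 for ends. Only the arrays compared gave 1 (distal maxilla), 761 (proximal maxilla) and 162 (proximal mandible). There fewer arrays estimate the spread, and arrays of other regions no longer enter it. The 12 mandible arrays gave 292 in the distal mandible, and the 12 control arrays 1035 for the control interaction. A stricter filter on dim genes gave 55 (distal mandible), 88 (regional average) and 674 (jaws), and quantile normalization 40 in the distal maxilla. The number as a block gave 80 (distal maxilla), 354, 1356, 1997 (jaws), 1677 (control ends) and 1013 (control interaction), and genotype with number 2522, 1912 and 1216 for the last 3. The regional average gave 235 with trended robust variances, 76 with a sex covariate, 2521 with 24 arrays as independent samples, 318 with a random block and 246 in the mandible alone. Tgfbr2 in the regional average kept its call in 11 of 20 settings. It no longer passed at 0.294 (mean of its probe sets), 0.471 (median centring), 0.459 (sex covariate) and 0.374 (covariates), nor without control 1, 2 or 3 (adjusted p = 0.146, 0.106 and 0.0931) or mutant 1 or 2 (0.0534 and 0.156). With covariates, Otx2 (0.457), Nhlh2 (0.0495), Insm1 (0.245) and Cldn9 (0.0605) reversed in the proximal maxilla, and Ttn (0.254) and Tgfbr2 (0.0534) for jaws, all short of the threshold. Sult1c1 (0.0889) reversed in the mandible alone. In the distal maxilla the cartilage list turned higher (camera adjusted p = 0.545 without the 3 arrays, 0.688 without mutant 1) and the muscle list lower (0.00142, 0.00268), and the nasal list for ends turned lower (0.722). Where the construction above does not show it, the cause was not tested.

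With each array left out in turn, counts ran from 7 to 61 (distal maxilla), 1363 to 3932 (proximal maxilla), 35 to 116 (distal mandible), 125 to 535 (proximal mandible), 6 to 341 (regional average), 448 to 2401 (jaws), 0 to 116 (ends), 4011 to 4397 (control jaws), 534 to 1215 (control ends) and 183 to 395 (control interaction), and Tgfbr2 from 0.407 to 0.494. The count moved by over 1.5 times without control 1 (8), 2 (61), 3 (7) or mutant 1 (11) in the distal maxilla, without control 1 (1950), mutant 1 (1363) or 2 (1568) in the proximal maxilla, without control 1 (51), 2 (58), mutant 1 (35) or 3 (48) in the distal mandible, and without control 1 (272), 2 (295), 3 (125) or mutant 1 (164) in the proximal mandible. For the regional average it was 6, 8 and 52 without control 1, 2 and 3 and 62, 7 and 341 without mutant 1, 2 and 3. For jaws it was 448, 506 and 2401 without mutant proximal maxilla 1, 2 and 3, 533 and 549 without control distal maxilla 1 and 3, 620 without control proximal maxilla 1, 629 without control distal mandible 1, 592 and 632 without control proximal mandible 1 and 3, and 670 and 646 without mutant distal mandible 1 and 3. For ends it was 116 without mutant distal maxilla 1 and 31 without mutant proximal maxilla 3. For control ends it was 534 without control distal maxilla 2 and 659 without control proximal maxilla 1. For the control interaction it was 316 and 288 without control distal maxilla 1 and 2, 292 and 300 without proximal maxilla 1 and 3, 300 and 298 without distal mandible 1 and 3, and 183 without proximal mandible 1. In the distal maxilla the camera adjusted p ran from 0.00346 to 0.688 for the cartilage list and from 2.25e-10 to 0.0814 for the muscle list. Other lists that no longer passed there were endothelium (0.794) and palate shelf (0.0654) without mutant 1, neuron (0.0504) without mutant 2, and nasal without control 1 (0.0917) or mutant 2 (0.0504). In the proximal mandible they were neuron (0.636), cartilage (0.0897), muscle (0.0565) and TGF-beta pathway (0.0565) without control 3, TGF-beta pathway without control 2 (0.0567), neuron (0.123) and muscle (0.17) without mutant 2, neuron (0.106) without mutant 3, osteoblast (0.0702) and TGF-beta pathway (0.128) without mutant 1, and neural crest mesenchyme without control 1 (0.122), control 3 (0.102) or mutant 3 (0.0663). In the distal mandible epithelium was lost in 1 of 6 fits (0.399, without control 2), osteoblast in 4 (up to 0.151) and tooth in 2 (up to 0.169). In the proximal maxilla matrix was lost in 2 of 6 (up to 0.329), tooth in 1 (0.0790) and maxillary patterning in 1 (0.0617), and in the regional average endothelium in 3 of 6 (up to 0.416), epithelium in 2 (up to 0.355) and Wnt in 2 (up to 0.0622). For jaws, cell cycle was lost in 16 of 24 fits, smooth muscle in 14, hedgehog in 13, Wnt in 6, hypoxia and glycolysis in 3 and lipid in 2. For ends, neural crest was lost in 8 of 24, osteoblast in 7, immediate early in 6, nasal in 4, cell cycle and lipid in 3 each and smooth muscle in 1. In controls, TGF-beta response was lost in 2 of 12 for jaws. For control ends matrix was lost in 7 of 12 (up to 0.440), osteoblast in 4 and glia in 1, and for the control interaction cartilage in 7, smooth muscle in 6, and neuron, palate shelf, immediate early and TGF-beta pathway in 1 each.

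Replicate numbers were not taken as pairs in the distal maxilla (correlations 0.0951 to 0.350, 3 of 3 best with their own number), the proximal maxilla (−0.0127 to 0.266, 2 of 3) and the control jaws (0.0248 to 0.360, 5 of 6), and blocks are a hint from the data there, not the design. Signal over background limits genes below the array median, whose changes are compressed.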

Other observations

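The test of neighbouring genes was chosen before its result was seen, and the sex-linked genes were checked to describe the samples.

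Genes around Tgfbr2 could differ if a stretch of chromosome from another strain had come with the targeted allele. Of the 100 nearest tested genes 12 had an unadjusted p under 0.05 in the regional average, and 86.4% of 10784 windows over the genome held as many, with a median of 16, which argues against a marked stretch. Itga9, 6 tested genes from Tgfbr2, was the only neighbour past the threshold (−1.07, adjusted p = 0.0309, limma), so a shorter stretch stays open for that gene.

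Xist was 12.5 to 13.3 in all 12 mutant arrays, with the Y-linked gene Eif2s3y between 8.13 and 9.59. In controls of number 1 Xist was 13.2 to 13.4 and Eif2s3y 7.47 to 8.41, and in controls of number 3 Xist was 6.28 to 6.66 and Eif2s3y 9.87 to 10.2. In controls of number 2 Xist was 13.0 in the distal maxilla, 12.6 in the distal mandible and 12.4 in the proximal mandible, with Eif2s3y at 9.20, 9.55 and 9.45, but 6.49 in the proximal maxilla, with Eif2s3y at 10.1. If the labels are right, that number therefore does not mark 1 embryo in all regions. High Xist together with Eif2s3y between number 1 and number 3 controls, as in most mutant arrays, is what material of both sexes would give. Low Xist occurred only among controls, in every region, so sex and genotype are not fully parted in the mutant comparisons. The count of the regional average was lower with a sex covariate, as given above. What a number marks is not given in the sources used here.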
